A study of Homo sapiens with 12 samples.

How the data were processed

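Human stromal cells, whose cell type label reads fibroblast, were cultured for 24 h with avelumab, atezolizumab, durvalumab or vehicle, with 3 libraries in each of the 4 groups. Per the labels' protocols, RNA was extracted with a column kit and polyadenylated RNA was made into stranded libraries with an Illumina TruSeq kit. Per the submitters' processing notes, the genome build was hg38. The aligner, the counting tool and their versions are not given in the sources used here. The labels number the libraries of each group 1 to 3 and do not say that these came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

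Each deposited table held 1 transcript per line with, per the file headers, total transcript reads and unique transcript reads as counts, together with TPM, RPKM and a relative RPKM. The relative RPKM, as deposited, is a fraction named in the file headers, whose values in the tables equal the RPKM divided by that of the gene's highest transcript, and was not used here. A complete table listed 153438 transcripts of 38654 gene names. The table of vehicle replicate 1 stopped partway along chromosome 17 after 125991 complete transcripts, and its unfinished last line was left out. As a result 31580 genes (81.7%) were complete in all 12 tables, and 7074 genes at the end of chromosome 17, on chromosomes 18 to 22, on X and Y and in the mitochondrial genome were complete in 11 tables. In the complete tables the deposited TPM values sum to 1000000. The read total behind each library was recovered from the deposited counts and RPKM of its transcripts, because RPKM is the count scaled by transcript length and by the library's read total, and it was used as the library size.

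For each gene, the total reads of its transcripts were summed. Whether reads shared by several transcripts or genes were counted more than once is not given in the sources used here, so genes with near-identical copies, readthrough transcripts and overlapping genes have uncertain counts. Summed counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr with a minimum count of 10, estimateDisp, a robust quasi-likelihood fit with 1 coefficient per group over all 12 libraries, and quasi-likelihood F tests with Benjamini-Hochberg adjustment at 0.05. The 12-library fit covered 13448 genes. Genes complete in 11 tables were tested in a fit of all chromosomes over 11 libraries, without vehicle replicate 1, with the adjustment made within 3173 genes. When another vehicle library was left out of that fit, the 1 vehicle library left was assumed to vary like the other groups. Fold changes are log2 ratios with the first-named group over the second, and expression is given as CPM, the count scaled to a library of 1000000 reads after TMM scaling, as mean and SD over 3 libraries.

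The comparisons were each antibody against vehicle, each pair of antibodies, and a test of any difference among the 4 groups. In addition, 32 gene lists covering immune checkpoints, interferon and NF-kB responses, matrix, metabolism, stress, growth and markers of 5 cell types were tested with limma 3.58.1. The tests were camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, which tests whether the genes of a list move one way on balance. Lists needed 5 tested members, and 31 lists qualified; the list of mitochondrially encoded proteins had 0 members in the tables. The groups, gene tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, except where an alternative is said to have been added later. List tests were fixed beforehand only for each antibody against vehicle. The plan did not hold the list tests between antibodies or the exact permutation of list means per library. Nor did it hold the Benjamini-Hochberg adjustment over the members of a list alone. Because of the incomplete table, the planned fit of all 12 libraries was applied to the genes complete in 12 tables.

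Named genes were CD274 in every group and, for each antibody against vehicle, the 12 highest and 12 lowest log2 fold changes that passed the test with a mean log2 CPM of at least 1 and all libraries of the groups apart. With fewer than 5 such genes, the 10 genes with the smallest unadjusted p were also named. For pairs of antibodies the rule took the 5 highest and 5 lowest. List members past the threshold, or the 2 members with the highest expression, could be named, and names without a symbol were left out. Unless the rule named them, members given as passing adjusted over their list alone were chosen after their values were seen. For other genes outside the rule, this is said where they are named.

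The alternatives were RLE normalisation, no filter on low counts, a mean CPM of at least 1, the replicate number as a block, reads unique to a transcript, the DESeq2 1.42.0 Wald test, limma on log2(TPM + 1), only the 2 groups compared, and each library left out in turn. Alternatives added after the data were seen were a correction for GC content and transcript length, all chromosomes in 11 libraries, and library sizes taken from the genes complete in 12 tables. Reads unique to a transcript made up 24.2% to 25.1% of the reads in each table, so that this alternative rests on fewer reads. For 90.2% of the tested genes a GC content was at hand. Other splits of the libraries were refitted with the same steps.

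Depth ranged from 43.1 M reads in durvalumab replicate 2 to 74.8 M in vehicle replicate 2. The steps were tested on simulated counts for the comparison of avelumab with vehicle over 13448 genes in 5 runs. Over all runs 250 genes each were changed 1.25-, 1.5-, 2- and 3-fold. The quasi-likelihood test found 67.2% of genes changed 1.25-fold, 92.8% of those changed 1.5-fold and 99.6% of those changed 2-fold. The mean number of false calls was 10.8 per run. With many changed genes the Benjamini-Hochberg threshold is looser. These rates therefore overstate what the test finds where few genes change, as in comparisons with 0 or 1 call. In a simulated comparison without changes the test made 1 call in all runs together. A list shifted by 0.2 on the log2 scale was called in 5 of 5 runs with the preset and with the estimated correlation. The simulated genes were drawn independently, so that members of a list did not move together. These runs therefore do not show how often either list test calls such a shift where members are correlated. In the real data the 95% confidence interval of a typical gene reached 0.132 to 0.133 to either side on the log2 scale, which is 1.1-fold. These intervals include the spread between libraries, whereas floors based on counts cover counting error only. No pair of libraries within a group differed by less than sampling noise: the chi-square per degree of freedom was 4.34 or more in each pair.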

Results

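Human stromal cells, labelled as fibroblasts, were exposed for 24 h to 1 of 3 antibodies against PD-L1, the checkpoint ligand encoded by CD274, and their polyadenylated RNA was sequenced. The groups were vehicle, avelumab, atezolizumab and durvalumab, with n = 3 libraries each. The series title places them in a study of how immune checkpoint inhibitors act on cells of the renal tumour environment. Library totals ranged from 43.1 M (durvalumab replicate 2) to 74.8 M (vehicle replicate 2) reads. The most abundant gene took 2.47% to 2.76% of the reads in the genes complete in all libraries.

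The cells expressed matrix, matrix protease and other fibroblast genes at high levels. MMP1, an interstitial collagenase, stood at 19960 ± 627 CPM (SD, n = 12 libraries) and MMP3, stromelysin, at 8634 ± 310 CPM. The intermediate filament gene VIM reached 4937 ± 176 CPM, FN1 (fibronectin) 2051 ± 176 CPM and the collagen I genes COL1A2 and COL1A1 1663 ± 88.3 and 1360 ± 102 CPM. Inflammatory genes were also abundant, with SOD2 at 1102 ± 79.5 CPM and CXCL8 at 1061 ± 100 CPM. MKI67, a proliferation marker, stood at 648 ± 48.2 CPM. Most markers of other cells had lower levels: the pericyte genes ABCC9 and CSPG4 had 83.3 ± 3.18 and 74.1 ± 5.4 CPM, the epithelial gene KRT18 54.3 ± 3.07 CPM, the kidney transcription factor PAX8 12.4 ± 1.14 CPM and the endothelial gene EGFL7 29.7 ± 2.14 CPM. The leukocyte gene PTPRC, chosen after its values were seen, had 0.0432 ± 0.038 CPM, whereas CD68, a lysosomal protein also made by fibroblasts, had 285 ± 22.8 CPM.

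The first question was whether the target of the antibodies was itself altered. CD274 (gene identifier 29126, chromosome 9, 5450503 to 5470567, hg38) was expressed at a low level in every group. Its mean was 4.47 ± 0.492 CPM with vehicle, 4.81 ± 0.289 with avelumab, 4.67 ± 0.305 with atezolizumab and 4.32 ± 0.347 with durvalumab (SD, n = 3 each). Against vehicle the log2 fold changes were 0.11 (SE 0.108), 0.067 (SE 0.108) and −0.051 (SE 0.109), with 95% confidence intervals of −0.114 to 0.334, −0.157 to 0.292 and −0.279 to 0.177. None passed edgeR's quasi-likelihood test (adjusted p = 1, 1 and 0.946). The sign for avelumab turned with reads unique to a transcript (−0.026) and with limma on TPM (−0.036). The sign for atezolizumab turned without vehicle replicate 2 (−0.0070), and that for durvalumab without vehicle replicate 1 (0.037) or durvalumab replicate 1 (0.012). Within the list of 13 tested checkpoint genes the most abundant members were NT5E, an ecto-nucleotidase, with 537 ± 3.65 CPM in vehicle and log2 fold changes of −0.023, 0.016 and 0.020 with avelumab, atezolizumab and durvalumab, and CD276 with 161 ± 7.69 CPM.

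**Figure D1:**
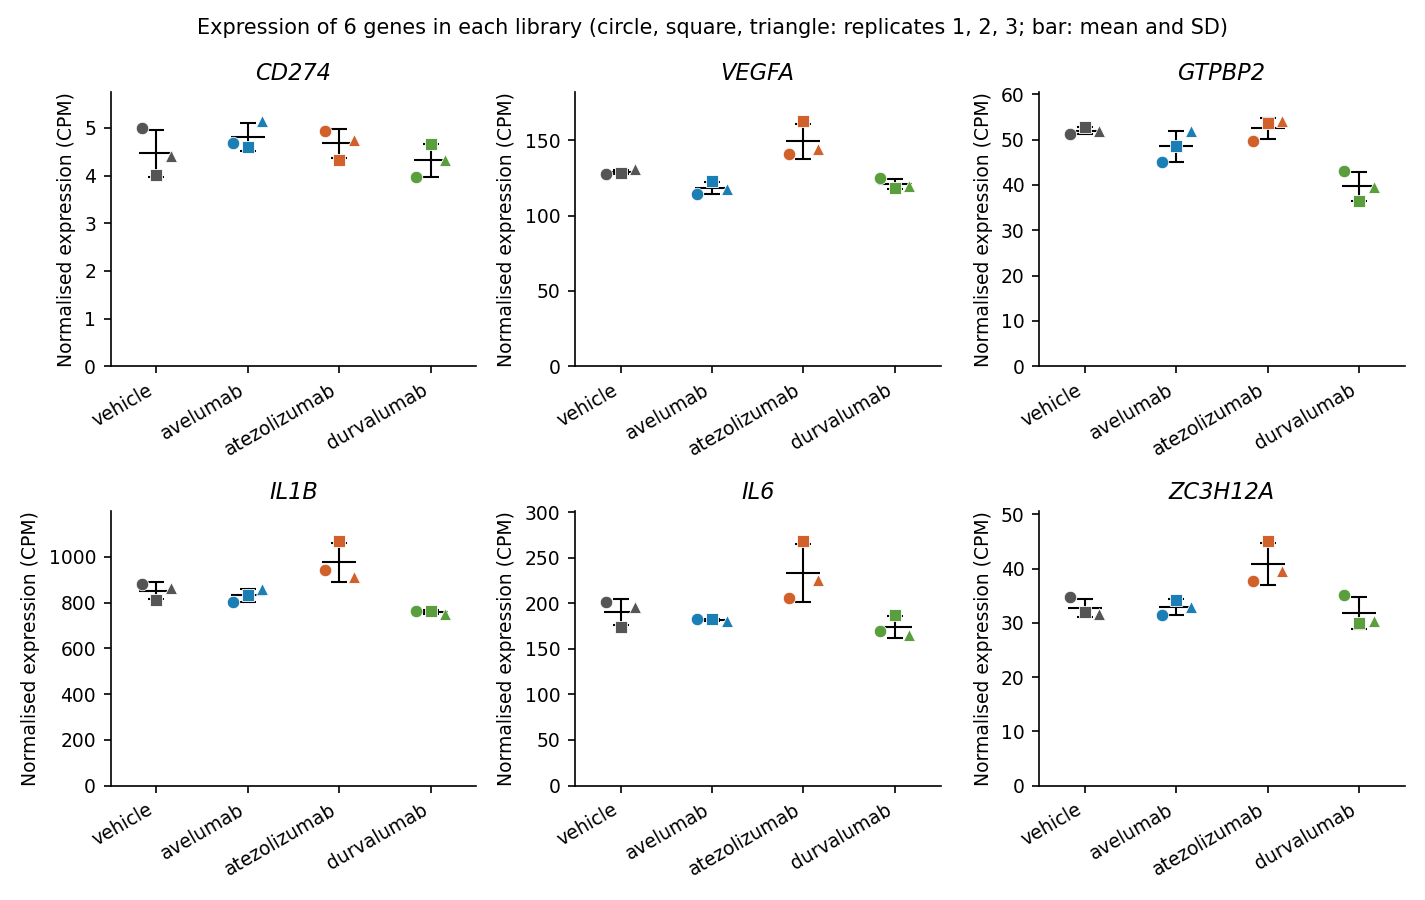
Normalised expression in CPM (vertical axis, from 0) of CD274, VEGFA, GTPBP2, IL1B, IL6 and ZC3H12A in each of the 12 libraries by group, with the mean and SD as bars. CD274 overlaps among the groups, the 3 durvalumab libraries lie below the 3 vehicle libraries for GTPBP2, and the 3 atezolizumab libraries lie above the 3 vehicle libraries for VEGFA, IL1B, IL6 and ZC3H12A.

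Avelumab, which carries an Fc part able to engage Fc receptors, left every one of the 13448 tested genes below the threshold. The gene with the smallest p was IQCJ-SCHIP1, a readthrough transcript, with 9.36 ± 0.142 CPM against 12.3 ± 0.159 in vehicle (log2 fold change −0.39, SE 0.0715, n = 3 each). Next came BIVM-ERCC5, another readthrough transcript, at −0.45 (SE 0.0908), and TMEM38B, an intracellular cation channel, at 0.19 (SE 0.0434; 60.8 ± 0.976 against 53.2 ± 1.08 CPM). The other genes among the 10 smallest p were SLC43A2 at −0.44, C1RL at −0.31, YOD1 at 0.25, UPF3A at −0.18, CITED4 at −0.36, RFK at 0.18 and SNX16 at 0.24. With edgeR's quasi-likelihood test 0 genes were called (smallest adjusted p = 0.312), 448 genes had an unadjusted p under 0.05 where chance gives 672, DESeq2 called 4 and limma on TPM called 0. The fit shares its spread over all groups, durvalumab included, and a spread too large for the groups compared lowers such counts. Here and below, a count under that of chance therefore does not show that an effect is absent. The sign of YOD1 turned with reads unique to a transcript (−0.073). Of the 13448 genes, 11.3% had all avelumab libraries on one side of all vehicle libraries, where chance gives 10%. Without avelumab replicate 2 or 3 the count was 1.

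The type I interferon response was the single list called with avelumab. Of its 36 tested members 30 lay below vehicle and 6 above, with a median log2 fold change of −0.061 (camera, adjusted p = 0.000178; adjusted p = 0.344 with an estimated correlation; fry, adjusted p = 0.388). Its most abundant member, IFIT3, an antiviral effector gene, stood at −0.025 (SE 0.0418; 255 ± 4.89 CPM in vehicle). No member passed over all genes or adjusted over the list alone (0 and 0 of 36). The median was −0.026 without avelumab replicate 1 and −0.040 without vehicle replicate 2.

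With atezolizumab, an antibody engineered to lack Fc receptor binding, cytokine and chemokine genes controlled by NF-kB were together above vehicle. Of the 29 tested members of this list 28 lay above vehicle, with a median log2 fold change of 0.19 (camera, adjusted p = 2.18e-16; adjusted p = 0.219 with an estimated correlation; fry, adjusted p = 0.108). Members that passed adjusted over the list alone numbered 15, against 0 over all genes. Among them were ZC3H12A, a ribonuclease that degrades cytokine transcripts, at 0.31 (SE 0.0704; 40.8 ± 3.89 against 32.8 ± 1.67 CPM) and IL1B at 0.20 (SE 0.0513; 976 ± 84.0 against 852 ± 36.3 CPM). IL6 stood at 0.295 (SE 0.0812; 233 ± 32.0 against 190 ± 14.4 CPM) and CXCL2 at 0.31 (SE 0.0797; 103 ± 10.8 against 82.9 ± 9.57 CPM).

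The mean of the NF-kB list, as the log2 difference from the vehicle mean, was 0.12, 0.36 and 0.14 in the 3 atezolizumab libraries and −0.031 to 0.023 in the vehicle libraries. The difference of 0.21 gave an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow. With avelumab and durvalumab the mean lay below vehicle, at −0.0667 and −0.0825 (exact permutation p = 0.2 each), which adds to the differences between antibodies given below. Without atezolizumab replicate 2 the median of the list was 0.12, with an adjusted p of 7.51e-10 from camera. The marker list of leukocytes, a possible source of such transcripts, had a median of −0.0575 over 7 members, and that of endothelial cells −0.070 over 9 members.

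A further 3 lists were called with atezolizumab. Inflammatory fibroblast markers had a median of 0.18, with 8 of 11 members above vehicle (camera, adjusted p = 0.008; adjusted p = 0.219 with an estimated correlation), and 4 members passed adjusted over the list alone: CXCL2, IL6, CXCL1 at 0.33 (SE 0.0960) and CCL2 at 0.37 (SE 0.118), all of them also in the NF-kB list. Its most abundant members, LMNA at −0.030 and the hyaluronan synthase gene HAS2 at −0.15, lay below vehicle. Immediate early genes had a median of 0.115, with 15 of 21 members above vehicle (camera, adjusted p = 0.00487; adjusted p = 0.219 with an estimated correlation; 0 members adjusted over the list alone). The type I interferon response had a median of 0.041, with 26 of 36 above vehicle (camera, adjusted p = 0.00302; adjusted p = 0.219 with an estimated correlation; 0 members adjusted over the list alone). The interferon call was lost without vehicle replicate 1 (median 0.028, adjusted p = 0.0693), and the call of inflammatory fibroblast markers without vehicle replicate 3 (median 0.067, adjusted p = 0.0749), while their median was 0.30 without vehicle replicate 1 and 0.31 without atezolizumab replicate 3. The immediate early call was lost without vehicle replicate 2 (median 0.067, adjusted p = 0.141) or atezolizumab replicate 3 (median 0.090, adjusted p = 0.122), and its median was 0.075 without vehicle replicate 1.

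**Figure D2:**
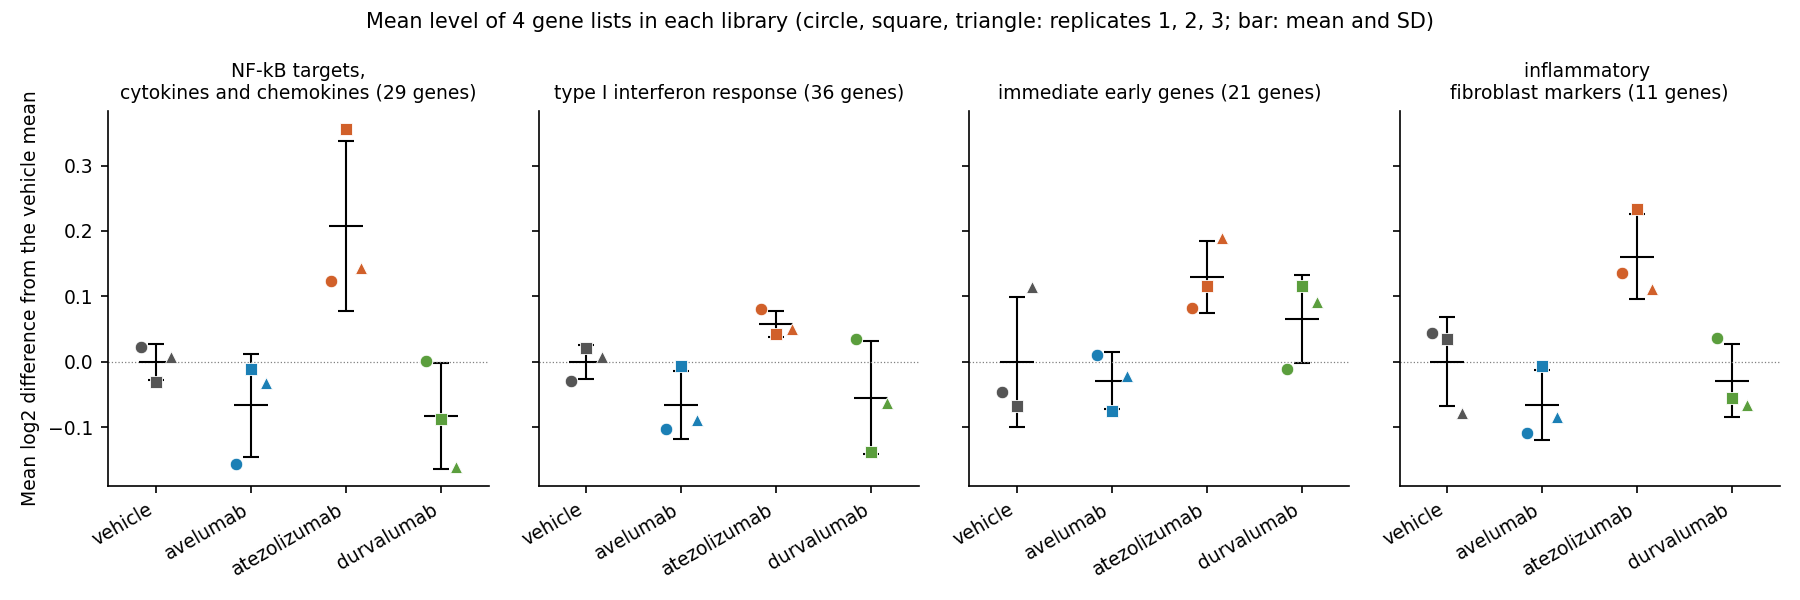
Mean log2 difference from the vehicle mean (vertical axis) over the tested members of 4 gene lists in each of the 12 libraries by group, with the mean and SD as bars. For the NF-kB list the atezolizumab libraries lie at 0.12, 0.36 and 0.14, above all 9 other libraries.

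Among single genes, 1 passed with atezolizumab. LOC107984832, a locus without an established symbol on chromosome 16 (29154296 to 29220856) in a region rich in near-identical copies, had 65 reads over the 3 atezolizumab libraries and 0 over the vehicle libraries, and was chosen after its values were seen. Its level of 0.373 CPM was at least 25.1-fold higher than the floor of 3 counts over the vehicle group (edgeR's quasi-likelihood test, adjusted p = 0.0298), and avelumab and durvalumab gave 4 and 21 reads. The 10 smallest p among named genes, none of which passed (adjusted p = 1), included VEGFA, the main angiogenic growth factor, at 0.21 (SE 0.0492; 149 ± 11.5 against 129 ± 1.57 CPM), CSF2 at 0.25, the bradykinin receptor gene BDKRB1 at 0.35, KLF4 at 0.22, the small nucleolar RNA host gene SNHG3 at 0.25 and the stress-response gene DDIT3 at −0.28. In all 433 genes had an unadjusted p under 0.05 where chance gives 672, DESeq2 called 2 genes and limma on TPM called 0. The call of LOC107984832 was lost without vehicle replicate 1, 2 or 3 (adjusted p = 0.346, 0.392 and 0.118), atezolizumab replicate 1, 2 or 3 (0.112, 0.191 and 0.265) or durvalumab replicate 3 (0.059), and 2 genes were called without avelumab replicate 2.

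With durvalumab, whose Fc part is mutated against receptor binding, 1 gene was called. GTPBP2, encoding a GTPase that rescues stalled ribosomes (chromosome 6, 43620481 to 43629246), had 39.7 ± 3.24 CPM against 52.0 ± 0.812 with vehicle, a log2 fold change of −0.39 (SE 0.0609; edgeR's quasi-likelihood test, adjusted p = 0.0433; lower in 3 of 3 libraries). No other gene of that fit passed, and PI4KAP1, among the genes complete in 11 tables, is given below. The next smallest p belonged to the pseudogene HERC2P9 at −0.63 (adjusted p = 0.0599) and to ABI3BP, an extracellular matrix gene, at −0.29 (969 ± 37.3 against 1183 ± 105 CPM; adjusted p = 0.119). GOLGA8A stood at −0.61, the ribosomal protein gene RPLP2 at 0.22 (386 ± 15.5 against 331 ± 10.7 CPM), MSH5-SAPCD1 at −0.95, PDXDC2P at −0.58, RBM4B at −0.32, GUCY1A2 at 0.24 (−0.125 with reads unique to a transcript), METTL17 at −0.28 and PARP6 at −0.30. Several of these (HERC2P9, GOLGA8A, PDXDC2P and MSH5-SAPCD1) share sequence with copies or neighbours, so that their counts are uncertain.

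In this comparison 1005 genes had an unadjusted p under 0.05 where chance gives 672, DESeq2 called 21 and limma on TPM called 0. The smallest p among the lists belonged to complement and Fc receptor genes, with 12 of 15 members below vehicle and a median of −0.096 (camera, adjusted p = 0.13; 1 member adjusted over the list alone). No list was called with durvalumab by camera, with an estimated correlation or by fry (0 of 31 each). GTPBP2 was not called without vehicle replicate 1, 2 or 3 (adjusted p = 0.13, 0.192 and 0.0793), avelumab replicate 2 (0.0558), atezolizumab replicate 1 or 3 (0.0625 and 0.0928) or durvalumab replicate 3 (0.333), and its fold change stayed between −0.445 and −0.334. Durvalumab replicate 2 stood apart from its group, with a root mean square log2 deviation of 0.176 where the other 11 libraries had 0.0925 to 0.129. Without it 8 genes were called, without durvalumab replicate 1 the count was 7, and without avelumab replicate 1 or 3 or atezolizumab replicate 2 it was 2.

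**Figure D3:**
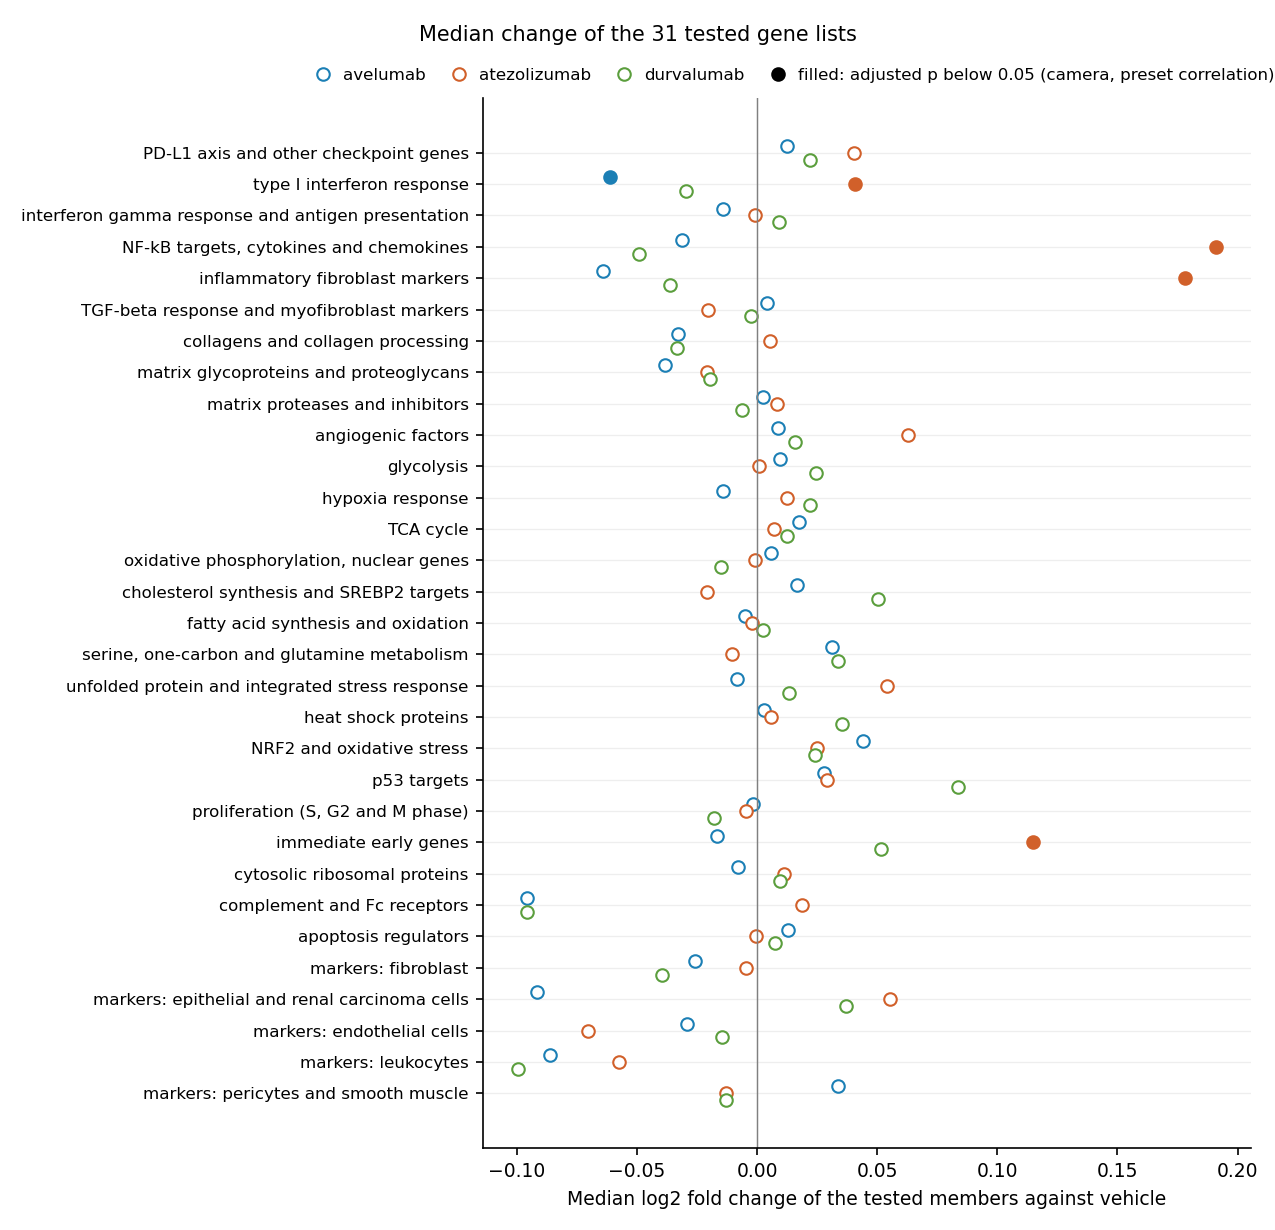
Median log2 fold change against vehicle (horizontal axis) of the tested members of each of the 31 gene lists with avelumab, atezolizumab and durvalumab. Filled points passed camera with the preset correlation: 1 list with avelumab, 4 with atezolizumab and 0 with durvalumab, while none passed with an estimated correlation.

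The other gene lists were not called against vehicle with any of the 3 antibodies. The lists of the TGF-beta response, collagens, matrix glycoproteins and matrix proteases had medians between −0.038 and 0.0085, and COL1A1 stood at 0.024, −0.035 and 0.022 and MMP1 at 0.010, −0.00075 and −0.0026 with avelumab, atezolizumab and durvalumab. The lists of glycolysis, hypoxia, the TCA cycle, oxidative phosphorylation, cholesterol synthesis, fatty acid metabolism and serine and one-carbon metabolism had medians between −0.021 and 0.050. Here GAPDH stood at 0.022, −0.022 and −0.082 and ADM at 0.043, −0.0074 and 0.13. The lists of the unfolded protein response, heat shock proteins, oxidative stress, p53 targets, proliferation, ribosomal proteins and apoptosis had medians between −0.018 and 0.084. The interferon gamma and antigen presentation list had medians of −0.014, −0.00079 and 0.0090, the angiogenic factors 0.0088, 0.063 and 0.016 (VEGFA alone passed adjusted over the list alone, with atezolizumab), and the complement and Fc receptor list −0.096, 0.019 and −0.096. For the 5 marker lists (fibroblasts, epithelial, endothelial, leukocytes, pericytes) the medians ran from −0.099 to 0.056. Means over a list's members in each library gave other values for some lists. For the epithelial markers with avelumab the mean was −0.21 ± 0.0339 (SD, n = 3; exact permutation p = 0.1). For the complement and Fc receptor list with durvalumab it was −0.212 ± 0.164 (exact permutation p = 0.2), with −0.402 in durvalumab replicate 2 and −0.123 and −0.112 in replicates 1 and 3. The smallest possible exact permutation p of 0.1 was also reached by p53 targets (0.0284, 0.0529 and 0.0425) and angiogenic factors (0.0265, 0.0825 and 0.0699) with avelumab, atezolizumab and durvalumab. It was reached as well by the oxidative stress list with avelumab (0.0511) and atezolizumab (0.0583), and by hypoxia (0.055) and serine and one-carbon metabolism (0.0424) with durvalumab. By chance alone a list reaches this exact permutation p with a probability of 0.1. The 3 antibodies were set against the same vehicle libraries, so a repeat across them is not independent. With this number of libraries a typical gene's 95% interval reached 0.132 or more to either side. Median, mean and test direction differed in sign for 9, 8 and 8 of the 31 lists with avelumab, atezolizumab and durvalumab, and 0 of these lists were called.

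Antibodies were next compared with each other in the same fit of all 12 libraries, so that every group helped to set the spread. The durvalumab libraries had root mean square log2 deviations of 0.126, 0.176 and 0.129, where the other libraries had 0.0925 to 0.126. With only avelumab and atezolizumab in the fit more genes were called, as given below. Few calls here thus do not show that these antibodies act alike. Between avelumab and atezolizumab, VEGFA (chromosome 6, 43770209 to 43786487) was lower with avelumab, at 118 ± 4.22 against 149 ± 11.5 CPM (log2 fold change −0.34, SE 0.0495; edgeR's quasi-likelihood test, adjusted p = 0.0159; lower in 3 of 3 libraries). The NF-kB list was lower with avelumab in 27 of 29 members, with a median of −0.24 (camera, adjusted p = 8.38e-15; adjusted p = 0.141 with an estimated correlation; fry, adjusted p = 0.0501), and 18 members passed adjusted over the list alone against 0 over all genes. Among them were CCL2 at −0.54 (SE 0.119), CXCL1 at −0.40 (SE 0.0968), IL6 at −0.36 (SE 0.0814) and IL1B at −0.23 (SE 0.0513). The type I interferon response was lower in 33 of 36 members, with a median of −0.12 (camera, adjusted p = 3.54e-10; adjusted p = 0.0987 with an estimated correlation; fry, adjusted p = 0.0237). Of these, IFIH1, a sensor of viral RNA, at −0.28 (SE 0.0719) and OAS2 at −0.21 (SE 0.0593) passed adjusted over the list alone.

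The other lists called between avelumab and atezolizumab were inflammatory fibroblast markers (median −0.35; adjusted p = 0.00283; adjusted p = 0.141 with an estimated correlation; 4 members adjusted over the list alone), immediate early genes (−0.12; 0.0034; adjusted p = 0.221 with an estimated correlation; 5 members adjusted over the list alone) and serine and one-carbon metabolism (0.038; 0.00563; adjusted p = 0.141 with an estimated correlation; 0 members adjusted over the list alone). Epithelial markers, whose 10 tested members had a median level of 1.55 CPM, were also called (median −0.175; adjusted p = 0.0349; adjusted p = 0.141 with an estimated correlation; 0 members adjusted over the list alone). All these p-values are from camera. VEGFA was not called without avelumab replicate 1, 2 or 3 (adjusted p = 0.399, 0.0535 and 0.129) or atezolizumab replicate 2 or 3 (0.208 and 0.0529), and the count was 3 without atezolizumab replicate 1 or durvalumab replicate 2 and 4 without durvalumab replicate 1. In this comparison 1008 genes had an unadjusted p under 0.05 where chance gives 672, DESeq2 called 16, and limma on TPM and reads unique to a transcript called 0.

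The immediate early call between avelumab and atezolizumab was lost without atezolizumab replicate 3 (adjusted p = 0.0676, camera). That of the epithelial markers was lost without avelumab replicate 1 or 3 (0.0751 and 0.143), atezolizumab replicate 3 (0.106, with a median of −0.10) or durvalumab replicate 2 (0.0506). The median of the inflammatory fibroblast markers was −0.22 without avelumab replicate 3, and that of serine and one-carbon metabolism 0.060 without avelumab replicate 1 and 0.067 without atezolizumab replicate 3.

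Avelumab and durvalumab did not differ in any single gene past the threshold. Epithelial markers were lower with avelumab in 8 of 10 members, with a median of −0.23 (camera, adjusted p = 0.0316; adjusted p = 0.278 with an estimated correlation; fry, adjusted p = 0.231; 0 members over all genes and 0 adjusted over the list alone). Their most abundant members, KRT18 and PAX8, had 52.9 ± 1.40 and 12.7 ± 1.16 CPM in vehicle. edgeR's quasi-likelihood test called 0 genes (smallest adjusted p = 0.0553), 803 genes had an unadjusted p under 0.05 where chance gives 672, DESeq2 called 10 and limma on TPM called 0, and without durvalumab replicate 2 the count was 9, without vehicle replicate 2 it was 2 and without vehicle replicate 3 it was 1. The list call was lost without avelumab replicate 1 or 3 (adjusted p = 0.0804 and 0.114) or durvalumab replicate 1 or 3 (0.151 and 0.217).

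Between atezolizumab and durvalumab, 38 genes were called by edgeR's quasi-likelihood test in the fit of all 12 libraries. Of these, 31 were higher and 7 lower with atezolizumab. The cytokine genes among them, chosen after their values were seen, were all higher with atezolizumab: IL1B at 976 ± 84.0 against 759 ± 7.17 CPM (log2 fold change 0.36, SE 0.0514, adjusted p = 0.00942), IL1A at 0.40 (SE 0.0681, adjusted p = 0.0192) and IL6 at 0.42 (SE 0.0816, adjusted p = 0.0494). ZC3H12A at 0.36 (adjusted p = 0.0372), VEGFA at 0.30 (149 ± 11.5 against 121 ± 3.21 CPM, adjusted p = 0.013) and GTPBP2 at 0.40 (52.5 ± 2.34 against 39.7 ± 3.24 CPM, adjusted p = 0.0119), chosen in the same way, were also higher. Each was higher in 3 of 3 libraries.

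The calls of these 6 genes also depended on single libraries, with adjusted p from edgeR's quasi-likelihood test. Without atezolizumab replicate 2 or durvalumab replicate 3, none was called: the values were 0.0502 and 0.0928 for IL1B, 0.214 and 0.145 for IL1A, 0.148 and 0.239 for IL6, 0.316 and 0.192 for ZC3H12A, 0.121 and 0.133 for VEGFA and 0.105 and 0.11 for GTPBP2. Without atezolizumab replicate 3 the calls of IL6 (0.12), ZC3H12A (0.0958) and GTPBP2 (0.0618) were lost. ZC3H12A was also lost without vehicle replicate 2 or 3 (0.0506 and 0.0556) or avelumab replicate 2 or 3 (0.0561 and 0.0537). IL6 was lost without vehicle replicate 1 or 3 (0.0513 and 0.0729), avelumab replicate 1, 2 or 3 (0.0598, 0.073 and 0.066) or durvalumab replicate 1 or 2 (0.0835 and 0.0848). The fold changes of IL1B stayed between 0.29 and 0.406 over all 12 libraries left out.

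By the naming rule, the largest differences upward were MSH5-SAPCD1 at 1.22 (SE 0.201; 2.39 ± 0.273 against 1.02 ± 0.043 CPM; adjusted p = 0.013), GOLGA8A at 0.77 (adjusted p = 0.0121), AGAP7P at 0.66 (0.0494), STAG3L5P-PVRIG2P-PILRB at 0.62 (0.0288) and HERC2P9 at 0.57 (0.0288), from edgeR's quasi-likelihood test. These 5 are pseudogenes, readthrough transcripts or members of repeated families, whose counts are uncertain. Downward they were AHNAK2 at −0.36 (272 ± 19 against 349 ± 36.6 CPM; adjusted p = 0.0443), the cadherin gene FAT4 at −0.35 (0.0443), LPP, a focal adhesion gene, at −0.29 (0.0443), CBX5, encoding heterochromatin protein, at −0.28 (0.0288) and RPLP2 at −0.22 (0.0366), from the same test. With reads unique to a transcript the sign of CBX5 turned (0.14).

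Of the lists, the NF-kB genes were higher with atezolizumab than with durvalumab in 28 of 29 members, with a median of 0.29 (camera, adjusted p = 1.87e-13; adjusted p = 0.25 with an estimated correlation; fry, adjusted p = 0.0574). Of these members 4 passed over all genes and 18 adjusted over the list alone. The type I interferon response had a median of 0.079, with 31 of 36 members higher (adjusted p = 7.65e-05; adjusted p = 0.25 with an estimated correlation), and STAT2 at 0.245 (SE 0.0546) was the 1 member that passed adjusted over the list alone. Complement and Fc receptor genes had a median of 0.135 (adjusted p = 0.037; adjusted p = 0.25 with an estimated correlation), and 2 members passed adjusted over the list alone, among them the complement protease gene C1S at 0.30 (SE 0.0688). Cholesterol synthesis (median −0.075; adjusted p = 0.0165; adjusted p = 0.311 with an estimated correlation) and serine and one-carbon metabolism (−0.046; 0.0165; adjusted p = 0.25 with an estimated correlation) were lower, with 0 members each adjusted over the list alone. These p-values are from camera where no other test is named.

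The count of 38 depended on single libraries. It was 0 without atezolizumab replicate 2 or durvalumab replicate 3, 4 without atezolizumab replicate 3, 12 without avelumab replicate 2, 25 without vehicle replicate 3, 122 without durvalumab replicate 1 and 252 without durvalumab replicate 2. The last of these libraries stood apart, as given above, and 34 of the 38 genes remained called without it; IL6 did not (adjusted p = 0.0848, edgeR's quasi-likelihood test). The split of 31 higher and 7 lower became 141 and 106 with DESeq2, 154 and 135 after the GC and length correction added later, 12 and 3 with unique reads, 4 and 0 with only the 2 groups (where avelumab and atezolizumab had 45 calls) and 2 and 0 with limma on TPM.

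Several list calls in this comparison also rested on single libraries, with adjusted p from camera. The complement call was lost without atezolizumab replicate 2 (0.202) or durvalumab replicate 2 or 3 (0.217 and 0.0811), and its median was 0.295 without durvalumab replicate 1. The cholesterol call was lost without atezolizumab replicate 2 (0.0568) or durvalumab replicate 2 or 3 (0.108 and 0.0811), with a median of −0.11 without durvalumab replicate 1. That of serine and one-carbon metabolism was lost without atezolizumab replicate 2 (0.0942) or durvalumab replicate 3 (0.199, with a median of −0.024).

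Across the 4 groups at once, 5 genes differed by edgeR's quasi-likelihood F test (smallest adjusted p = 0.0282), 1038 had an unadjusted p under 0.05 where chance gives 672, DESeq2 called 106 and limma on TPM called 0. The first principal component held 14.4% of the variance and set durvalumab replicate 2 apart from the other 11 libraries. The count of 5 became 0 without vehicle replicate 1, avelumab replicate 1, atezolizumab replicate 2 or 3 or durvalumab replicate 3, and 10 without vehicle replicate 3, 8 without avelumab replicate 3, 19 without durvalumab replicate 1 and 52 without durvalumab replicate 2. The share of a gene's variance between the groups had a median of 27.5% over 9704 genes. Without any effect the mean of that share is 27.3%. A median and a mean of such a skewed share differ, so these values do not show that an effect is absent. No gene was called with the same sign for more than 1 antibody against vehicle. With 0 calls for avelumab, 1 higher for atezolizumab and 1 lower for durvalumab, none could be.

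**Figure D4:**
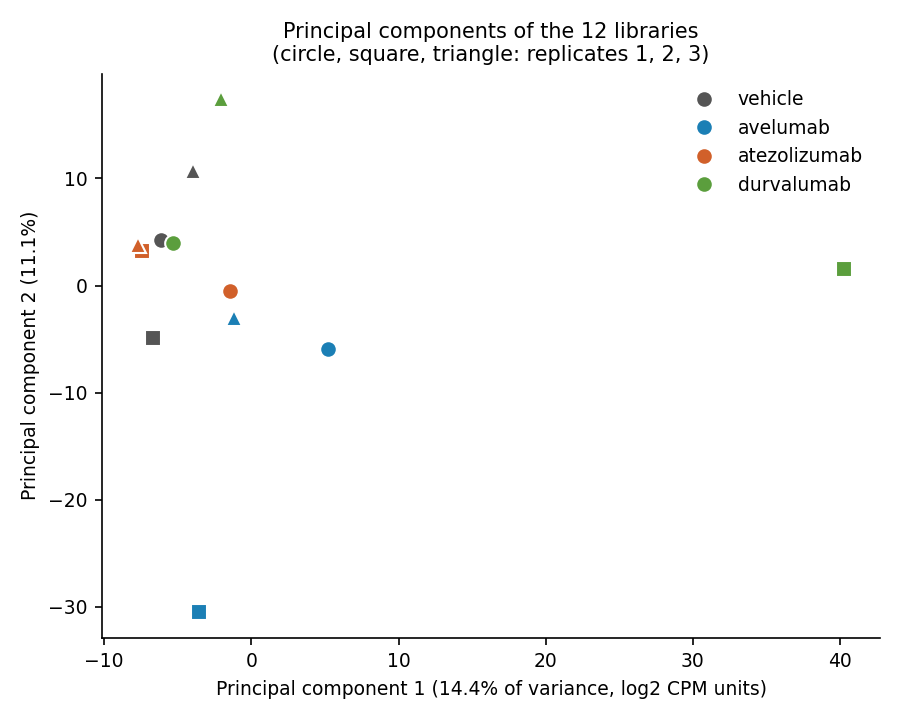
Principal components 1 and 2 of log2 CPM (axes in log2 CPM units, with 14.4% and 11.1% of the variance) for the 12 libraries, coloured by group. Durvalumab replicate 2 lies far to the right of the other 11 libraries, and the groups overlap.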

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

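Results under the alternatives were counted for the genes named by the rule and for the lists called against vehicle. IL1B, IL1A, IL6, VEGFA, ZC3H12A and LOC107984832, where chosen after their values were seen, were added. Other chosen genes and the lists called between antibodies are not in these counts. In all, 454 results kept their direction and their side of the threshold, including those of genes that never passed and stayed uncalled. A further 82 kept the direction but no longer passed, 43 kept the direction and came to pass, and 8 turned direction. The fits that leave out 1 library were counted once per result. Those that turned were CD274 with avelumab (−0.0264 with reads unique to a transcript, −0.0357 with limma on TPM), CD274 with atezolizumab (−0.00696 with 1 library left out) and CD274 with durvalumab (0.0119 without durvalumab replicate 1 and 0.0366 without vehicle replicate 1, 0.0371 with all chromosomes in 11 libraries). With unique reads, YOD1 with avelumab (−0.0726), GUCY1A2 with durvalumab (−0.125) and CBX5 between atezolizumab and durvalumab (0.144) also turned. The cause was not tested.

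Without a filter on low counts, called genes were 33 with avelumab (16 higher, 17 lower), 70 with atezolizumab (37 and 33) and 141 with durvalumab (38 and 103) against vehicle. Between antibodies they were 126 for avelumab and atezolizumab (53 and 73), 113 for avelumab and durvalumab (60 and 53) and 390 for atezolizumab and durvalumab (212 and 178), with 26 shared calls and 364 genes among the 4 groups. On the remaining chromosomes the counts in the same order of comparisons were 9, 13, 22, 21, 27 and 63. With a mean CPM of at least 1 the count with atezolizumab was 0, because LOC107984832 lies below that level.

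DESeq2 called 4 genes with avelumab (1 higher, 3 lower), 2 with atezolizumab, 21 with durvalumab (5 and 16), 16 between avelumab and atezolizumab (2 and 14), 10 between avelumab and durvalumab and 247 between atezolizumab and durvalumab. It gave 2 shared calls and 106 genes among the 4 groups, and on the remaining chromosomes 1, 2, 2, 2, 7 and 19 genes. limma on TPM called 0 genes with atezolizumab, 0 with durvalumab, 0 between avelumab and atezolizumab, 2 between atezolizumab and durvalumab and 0 among the 4 groups. With only the 2 groups compared, which leaves fewer libraries to estimate the spread, the counts were 1 with avelumab, 2 with atezolizumab, 45 between avelumab and atezolizumab and 4 between atezolizumab and durvalumab. Apart from the low-expression case, the cause of these shifts was not tested.

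With reads unique to a transcript the counts were 0 between avelumab and atezolizumab, 1 between avelumab and durvalumab and 15 between atezolizumab and durvalumab, and on the remaining chromosomes 2 with atezolizumab and 2 with durvalumab. Libraries with the same number did not in general resemble each other more. Their 18 correlations lay between −0.0432 and 0.0624, where pairs with other numbers lay between −0.0652 and 0.0649. Of 12 libraries, 5 correlated best with their own number. All pairs of replicate 3 lay above 0, at 0.0227 to 0.0624, so a small shared part in those libraries is not excluded. With the number as a block the counts were 3 with durvalumab, 2 between avelumab and atezolizumab, 2 between avelumab and durvalumab, 79 between atezolizumab and durvalumab, 1 shared and 8 among the 4 groups, and on the remaining chromosomes 0 with durvalumab and 4 between atezolizumab and durvalumab.

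Alternatives added after the data were seen moved counts too. After correction for GC content and transcript length the counts were 2 with durvalumab, 3 between avelumab and atezolizumab, 3 between avelumab and durvalumab, 289 between atezolizumab and durvalumab and 56 among the 4 groups. List calls with the correction were 2 with avelumab, 7 with atezolizumab and 3 with durvalumab. With all chromosomes in 11 libraries, 0 genes were called with atezolizumab, 0 with durvalumab and 2 between avelumab and atezolizumab, and 1 list was called with durvalumab. The list counts with avelumab and atezolizumab, 1 and 4, became 0 and 0 with an estimated correlation and 0 and 0 with fry.

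With 1 library left out, the counts ran from 0 to 1 with avelumab, 0 to 2 with atezolizumab, 0 to 8 with durvalumab, 0 to 4 between avelumab and atezolizumab, 0 to 9 between avelumab and durvalumab, 0 to 252 between atezolizumab and durvalumab and 0 to 52 among the 4 groups. List calls ran from 1 to 4 with avelumab, 3 to 5 with atezolizumab and 0 to 3 with durvalumab, and shared calls from 0 to 1. On the remaining chromosomes the ranges were 0 to 0, 0 to 2, 0 to 5, 0 to 2, 0 to 54 and 3 to 94 in the order of comparisons above.

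Of the 38 genes called between atezolizumab and durvalumab, 38 remained called without a filter, 38 with library sizes from the complete genes, 37 with DESeq2, 36 with RLE, 36 with the block, 34 after the GC and length correction, 24 with all chromosomes in 11 libraries, 13 of 34 tested with unique reads, 2 with limma on TPM and 2 with only the 2 groups compared. The sign was kept in all of these except with unique reads, which are fewer, where 30 of 34 kept it. Depth sets a limit for genes with few reads such as LOC107984832, with 65 reads over the atezolizumab group.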

Other observations

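Genes of the remaining chromosomes, complete in 11 tables, were compared without vehicle replicate 1, and those named here were chosen after their values were seen. With atezolizumab 8 genes were higher than with durvalumab and 0 lower. Among them were PABPC1L, a poly(A)-binding protein gene on chromosome 20, at 0.66 (SE 0.0834, adjusted p = 0.000777, edgeR's quasi-likelihood test), the readthrough transcript RTEL1-TNFRSF6B at 0.76 (SE 0.101, adjusted p = 0.000777) and the pseudogene PI4KAP1 on chromosome 22 at 0.83 (SE 0.127, adjusted p = 0.00362). LIF, an interleukin 6 family cytokine gene, stood at 0.28 (SE 0.0525, adjusted p = 0.0217) and COX7B, a respiratory chain gene, at 0.26 (SE 0.0479, adjusted p = 0.0217). LIF and COX7B were lost without avelumab replicate 2 or 3 (adjusted p = 0.0542 and 0.0516 for both), atezolizumab replicate 2 or 3 (0.265 and 0.131 for both) or durvalumab replicate 3 (0.132 and 0.118). The count was 3 without avelumab replicate 2 or 3 or atezolizumab replicate 3, 4 without atezolizumab replicate 2 or durvalumab replicate 3 and 94 without durvalumab replicate 2.

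PI4KAP1 was also lower with durvalumab than with vehicle (−0.83, SE 0.137, adjusted p = 0.0279, edgeR's quasi-likelihood test), and RTEL1-TNFRSF6B lower with avelumab than with atezolizumab (−0.70, SE 0.1, adjusted p = 0.00411). Without vehicle replicate 2 or 3 the vehicle group held 1 library, assumed to vary like the other groups. PI4KAP1 then stood at −0.578 without vehicle replicate 2 and at −1.04 without vehicle replicate 3. Its fold change thus depended on which vehicle library was left, and these fits say little else. PI4KAP1 was lost without avelumab replicate 2 (0.0638), atezolizumab replicate 1, 2 or 3 (0.0638, 0.0737 and 0.0654) or durvalumab replicate 3 (0.179), and RTEL1-TNFRSF6B without avelumab replicate 2 (0.0763) or atezolizumab replicate 2 or 3 (0.0633 and 0.0694). edgeR called 0 genes with avelumab, with atezolizumab and between avelumab and durvalumab, where 61, 80 and 180 of 3173 genes had an unadjusted p under 0.05 (chance gives 159) and DESeq2 called 1, 2 and 7. Without durvalumab replicate 2, 54 genes were called between avelumab and durvalumab.

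In the weighing of the NF-kB list the tests of a single library and of ordinary variation were chosen after the result was seen. The list was higher with atezolizumab than with vehicle, with a median of 0.191. After correction for GC content and transcript length the median was 0.172, which argues against such a bias as the whole cause. The leukocyte markers had a median of −0.0575, which by the criterion set beforehand goes against RNA from leukocytes. Only 7 of the 16 such markers complete in 12 tables were tested, with a median level of 2.45 CPM. The most abundant, CD68 at 285 CPM, stood at 0.044 (SE 0.0685) with atezolizumab. The list median is thus weak evidence. PTPRC had 0.0432 CPM over the 12 libraries. With any 1 atezolizumab or vehicle library left out the mean difference was at least 0.133, against a single library carrying the list, while ordinary variation between cultures may account for it and stays open (adjusted p = 0.219, camera with an estimated correlation).

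In the weighing of the genes that differed between atezolizumab and durvalumab the test without durvalumab replicate 2 was chosen after the result was seen. Correction for GC content and transcript length left 289 genes called, of which 34 were among the 38, and 252 genes were called without durvalumab replicate 2, again with 34 of the 38. Neither result is one that the bias or that library alone would give. Reads outside the transcripts made up 7.14%, 7.99% and 7.48% with durvalumab (mean 7.53%) and 7.3%, 7.13% and 6.82% with atezolizumab (mean 7.08%). By the criterion set beforehand, a durvalumab mean at or above that of atezolizumab goes against less unspliced or intergenic RNA in the durvalumab libraries. The values of single libraries overlap, so that a small difference is not excluded. A difference in culture between the groups was not tested, and an effect of the antibodies is a hypothesis only.

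Durvalumab replicate 2 stood apart from the other libraries, and both tests of it were chosen after it had been seen to stand apart, before their own values were seen. Among genes above 100 CPM its root mean square log2 deviation was 1.63 times that of the next library (0.131 against 0.0799), so that its low depth is not the whole cause. That next library was durvalumab replicate 1, whose deviation from the group mean replicate 2 itself raises. GC content and transcript length accounted for 51.6% of the variance across genes of its deviation from the other 2 durvalumab libraries. For its deviation from the mean of all libraries the share was 42.4%, against 22.3% in durvalumab replicate 1, 18.3% in atezolizumab replicate 3 and 1.02% to 12.1% in the other 9. The share of 51.6% narrowly met the criterion for such a bias set before its value was seen, a share over 50%. The share of 42.4% is another measure, outside that criterion. Such a bias may thus be part of the cause, and whether it is the whole cause stays open. EGR1, an immediate early gene, was 0.831 higher in it than in its group on the log2 scale, and the matrix gene HSPG2 was 0.552 lower and the receptor gene LRP1 0.518 lower (chosen after their values were seen).

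The splits of 6 libraries into 3 and 3, the real one included, number 10, too few for a share under 0.05. For genes, the real split and the highest other split gave 0 and 1 with avelumab, 1 and 1 with atezolizumab, 1 and 0 with durvalumab, 1 and 1 between avelumab and atezolizumab, 0 and 2 between avelumab and durvalumab, and 38 and 30 between atezolizumab and durvalumab. As many genes as in the real split were found in 10, 3, 1, 2, 10 and 1 of the 10 splits. For lists the pairs were 1 and 2, 4 and 3, 0 and 5, 6 and 5, 1 and 7, and 5 and 5, with as many lists in 7, 1, 10, 1, 7 and 2 of the 10 splits. On the remaining chromosomes they were 1 and 0 between avelumab and atezolizumab, 0 and 2 between avelumab and durvalumab and 8 and 0 between atezolizumab and durvalumab (1, 10 and 1 of the 10 splits). For the 4 groups, 5 of 100 regroupings gave 5 or more genes and the highest other gave 25, so chance was not excluded.

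Fold changes against vehicle share the 3 vehicle libraries, which alone makes them correlate. Over 9719 genes the correlation was 0.231 between avelumab and atezolizumab, 0.445 between avelumab and durvalumab and 0.143 between atezolizumab and durvalumab. In 10 simulations without any effect it averaged 0.5 (0.364 to 0.645), 0.519 (0.396 to 0.658) and 0.466 (0.267 to 0.651). The covariances were 0.00148, 0.00366 and 0.00119, against simulated means of 0.00487 (lowest 0.00389), 0.00509 (lowest 0.00338) and 0.00454 (lowest 0.00264). None exceeded its simulated mean, and the values of both pairs with atezolizumab lay below the lowest simulation. The simulations gave each gene 1 dispersion, estimated over all 12 libraries, durvalumab replicate 2 included. Without effects the covariance rests on the vehicle libraries. Their root mean square log2 deviations were 0.101, 0.0925 and 0.126, against 0.176 in durvalumab replicate 2. The simulated values may thus be too high, and no conclusion is drawn from the lower observed values. The cause was not tested.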
